A study of Mus musculus with 12 samples.

How the data were processed

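Total RNA of 12 livers from germ-free male C57BL/6J mice was sequenced. Per the labels' protocols, RNA was extracted with a guanidinium thiocyanate buffer, 250 ng were made into libraries with a stranded total RNA kit after depletion of ribosomal RNA and amplified for 12 PCR cycles, and the libraries were read for 125 cycles from each end. The deposited values are raw counts of reads over the exons of each gene, as whole numbers that the authors did not normalise. Per the submitters' processing notes, reads were aligned with STAR 2.4.0i to mm10. The counting tool, its annotation release, its strand setting and its treatment of reads that map to several places are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes carry an uncertainty that the counts cannot resolve.

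The group and number of each library come from its title and treatment label. Each library is treated as 1 animal, although no label says that each comes from a separate one; where that does not hold, p-values measure only the spread between these samples, which can be technical. No label names a cage, litter or day, and the shared numbers of the groups are not said to pair animals and were not used as pairs. Pairs of libraries within a group differed by 11.6 to 48.5 times the variance that counting error gives (chi-square per degree of freedom), so none was the same library deposited again; separate preparations from 1 animal would not be detected this way. Total counts per library were 15775059 to 22302533, and 27410 of 38087 genes had a count in some library. PCR copies are not independent molecules, and counting limits cover counting error only.

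Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 14170 genes. TMM factors were computed, dispersions estimated (biological coefficient of variation 0.145), and the 6 ghrelin libraries compared with the 6 PBS libraries by the quasi-likelihood F test without robust estimation, two-sided, in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are ghrelin over PBS, and their SE is the absolute log2 fold change divided by the square root of F. CPM values use the TMM factors and are given as mean ± SD over 6 animals. Values on the log2 CPM scale use a prior count of 2.

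Gene lists were written before the data were examined: 35 lists for sex-biased expression, hormone signalling, metabolism, clock, stress and cell types. Of these, 33 had at least 3 measured members and were tested; mitochondrially encoded genes were not analysed here, and the pancreatic acinar markers lay below the count filter, Cela2a with 122 counts over all libraries having the most. Lists were compared with the other genes by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation; fry tested whether the members of a list move in the same direction without comparing them with other genes. Counts adjusted over the list alone use the gene p-values of the list only. The sex index and other values with 1 number per animal were compared by exact two-sided permutation over all 924 assignments, whose smallest possible p is 0.00216.

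The genes named were set by a rule fixed before the data were examined. They are the up to 15 highest and 15 lowest log2 fold changes among called genes with a symbol that is not a model name, a mean of at least 1 CPM and group means that differ in the direction of the fold change. The rule adds up to 4 measured members of each list with the smallest unadjusted p, of which the text gives a part, and preset genes of growth hormone signalling, sex bias, metabolism and the clock. Had fewer than 10 genes passed, the 10 with the smallest p in each direction would have been added. Some genes that the rule takes in, 1 called gene among them, are not reported here. The 2 called genes with model names, Dio1, Cyp2c44, Cyp2c67, Cyp2c68, Cyp2c70, Ghsr, Ghrl, Mboat4, Cela2a and the genes at the ends of the principal component axis were named after their values were seen. Gene positions, types, transcript lengths and GC content come from GENCODE M21 on GRCm38, matched by Ensembl identifier, which covered 98.3% of the tested genes; the longest transcript gave length and GC content.

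On counts simulated from the means, library sizes and dispersions of these 14170 genes for 6 against 6 libraries, with 200 genes changed, the test recovered 50% of 50 genes changed by a log2 fold change of 0.5, 82% of those changed by 1, 94% by 1.5 and 100% by 2. It made 14 calls among unchanged genes, 7.91% of its calls, and 0 calls where nothing was changed. Each gene was drawn independently, without variation that genes share within an animal, so these rates need not hold for the real libraries. Alternatives fixed before the data were examined were other scalings, filters, removal of the top 50 genes with the urinary protein genes, robust estimation, a replicate block, voom with and without quality weights, DESeq2 1.42.0, 1 surrogate variable (sva 3.50.0), an adjusted p under 0.1, other list tests and the removal of each library. For the 10 lists past the threshold other than the male- and female-biased ones, the other list tests were the alternatives fixed beforehand, and the rest were applied to them after seeing the data. Added after seeing the data were also the removal of GC and length trends per library (lowess offsets), alone and with the replicate block, the acute phase mean as a covariate, and the fit without PBS 3, PBS 4 and ghrelin 4, the libraries with the highest counts of the acute phase gene Saa2. Figures were drawn with matplotlib 3.10.9.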

Results

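Liver RNA was measured in 12 germ-free male C57BL/6J mice, animals raised without any microbiota, at 13 to 16 weeks of age. The ghrelin group (n = 6) received rat ghrelin under the skin once a day for 5 days at a dose of 10 µg per mouse, and the PBS group (n = 6) received phosphate-buffered saline. Ghrelin is a peptide hormone of the stomach that stimulates feeding and the release of growth hormone from the pituitary through its receptor Ghsr. Injection and sampling are both labelled zeitgeber time 2, that is 2 h after lights on. Total counts over genes ranged from 15775059 to 22302533 per library, with a mean of 20959324 ± 1378600 (SD, n = 6) for PBS and 18536889 ± 2398783 (SD, n = 6) for ghrelin. The difference of -2422435 counts had an exact two-sided permutation p of 0.0671. The comparison asks which liver transcripts differ after repeated ghrelin in males that lack a microbiota, including the sex-biased transcripts that depend on the pattern of growth hormone secretion.

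Few single genes passed the test. Of 14170 genes tested, 15 passed the threshold, 6 higher and 9 lower with ghrelin. The largest rise was that of Cyp2c40, a cytochrome P450 that is higher in female than in male liver, from 7.56 ± 1.95 to 33.5 ± 22.8 CPM (SD, n = 6 per group), a log2 fold change of 2.15 (SE 0.34, adjusted p = 0.0263). Osgin1, an oxidative stress-induced growth inhibitor, rose from 26.1 ± 5.46 to 58.6 ± 19.1 CPM (log2 fold change 1.16, SE 0.20, adjusted p = 0.0379). Hes1, a transcriptional repressor of the Notch pathway, rose by a log2 fold change of 0.71 (SE 0.12) and Cbx2, a subunit of Polycomb repressive complex 1, by 0.65 (SE 0.10). Stard13, a GTPase-activating protein, rose by 0.42 (SE 0.08, adjusted p = 0.0472). The transcript 1810019D21Rik, whose model name lies outside the naming rule and which is named after its value was seen, rose by 0.84 (SE 0.12). Of the 9 genes that fell, Serpina7 changed most. It encodes thyroxine-binding globulin, a carrier of thyroid hormone in plasma, and went from 87.8 ± 17.0 to 32.8 ± 11.5 CPM (log2 fold change -1.42, SE 0.21, adjusted p = 0.0206).

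Among the other genes that fell, Ccrn4l, also named Noct, encodes the rhythmically expressed RNA-binding protein nocturnin. It went from 21.4 ± 6.29 to 9.40 ± 2.12 CPM (log2 fold change -1.18, SE 0.18, adjusted p = 0.0244). Slco1a4, an organic anion transporter that is higher in female liver, had a log2 fold change of -1.03 (SE 0.17), and Slc38a2, a transporter of neutral amino acids, of -0.74 (SE 0.12). Ppp1r10, a regulatory subunit of protein phosphatase 1, fell by 0.61 on the log2 scale (SE 0.11), Dnajb4, a co-chaperone of Hsp70, by 0.56 (SE 0.08), and Cyp2c37, a cytochrome P450 that metabolises arachidonic acid, by 0.55 (SE 0.09). The transcript 1810011O10Rik, named Tcim in the later annotation and also named after its value was seen, fell by 0.83 (SE 0.13). In 13 of the 15 genes no PBS value overlapped a ghrelin value. Over all tested genes 117, or 0.826%, were without overlap, against 0.216% by chance. At an unadjusted p under 0.05 there were 1896 genes, 913 higher and 983 lower, where 708 would be expected by chance. Another grouping of the same libraries, which mixed the treatments, gave 1950. The excess over 708 therefore cannot be read as an effect of ghrelin alone.

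The number of calls rested on single animals. The quasi-likelihood test of edgeR called 0 genes without the library ghrelin 1 (1675 genes at an unadjusted p under 0.05), 0 without ghrelin 3 (1536 genes), 5 without PBS 3, 6 without ghrelin 6, 9 without ghrelin 2, 23 without PBS 6, 24 without PBS 5 and 32 without ghrelin 4. It called 5 genes, all among the 15, once trends with GC content and transcript length were removed; the log2 fold changes of the 15 were then 0.857 to 1.07 times and their SEs 0.892 to 1.12 times those before, and their adjusted p lay from 0.0453 to 0.0709. DESeq2 called 204 genes, which included all 15. Each of the 15 genes kept its sign in all 28 alternative fits that gave it a value, and was called in 14 to 25 of them.

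**Figure D1:**
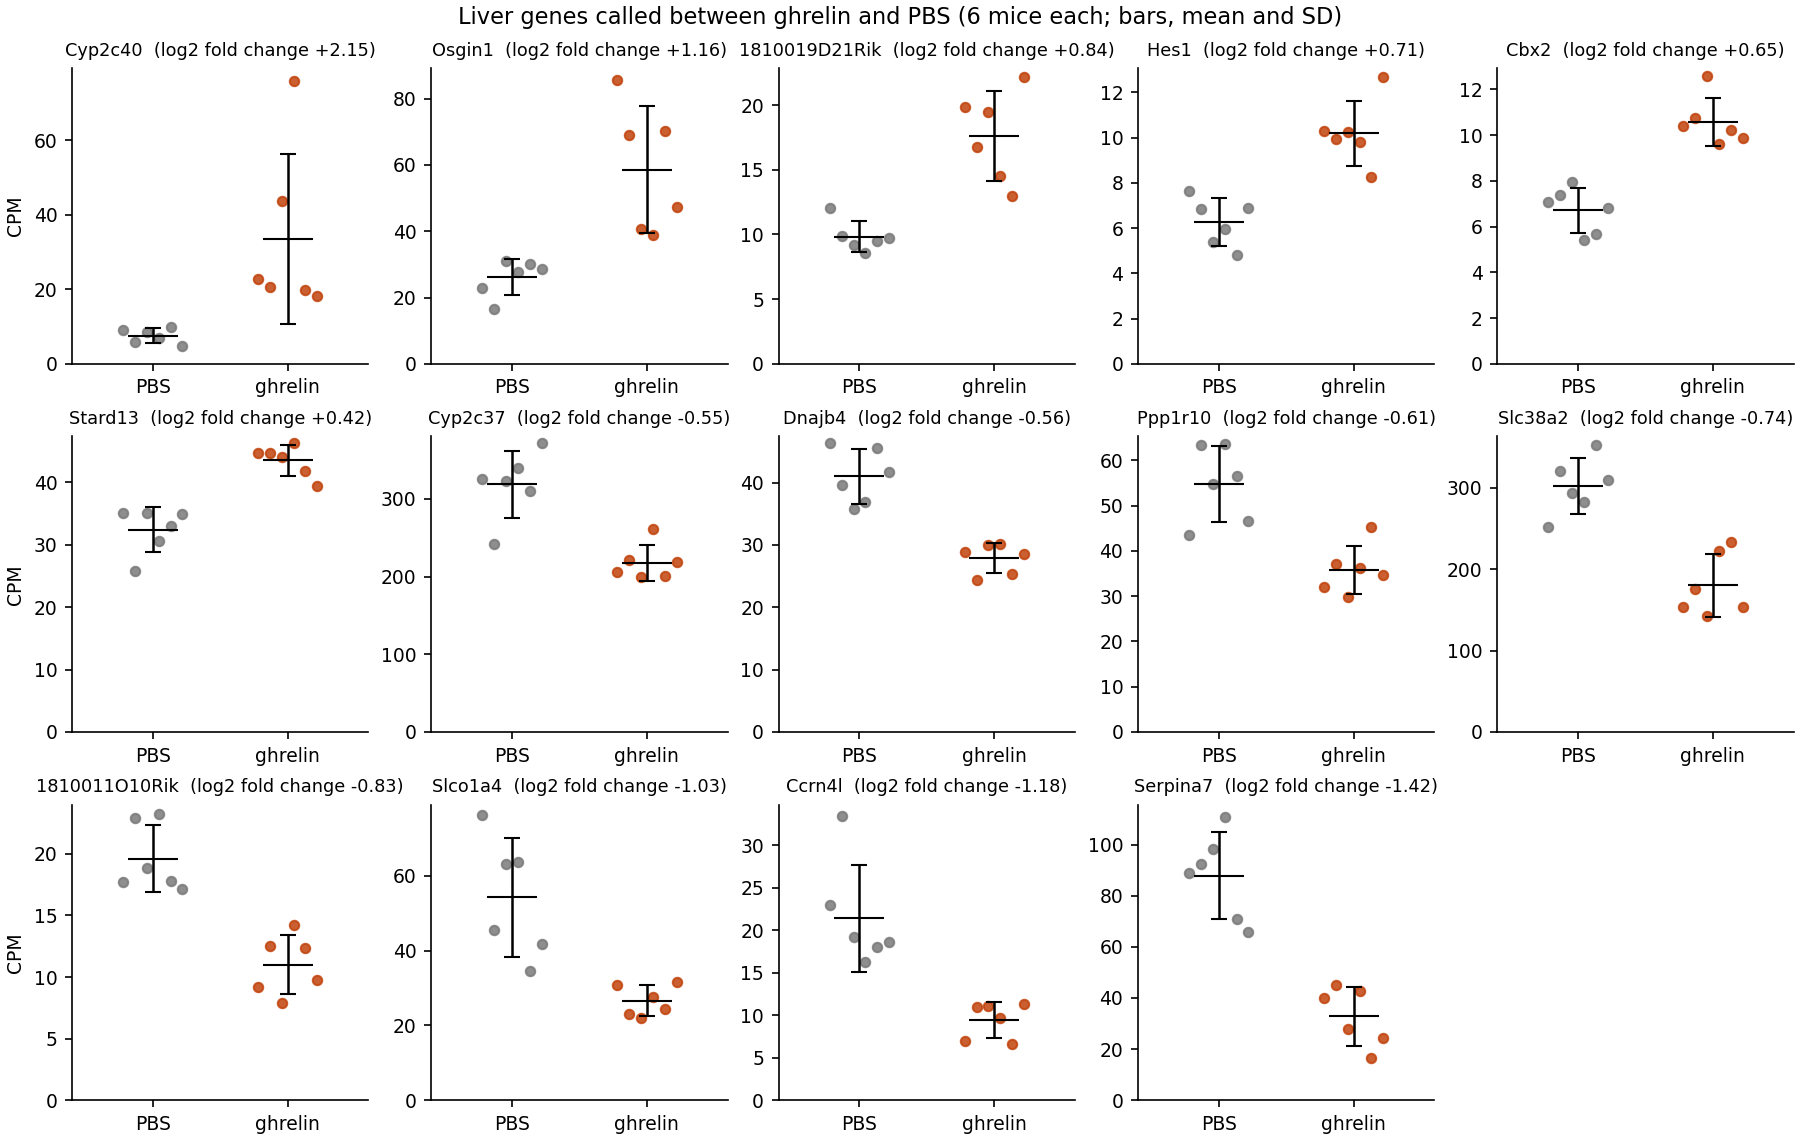
CPM of 14 of the 15 genes past an adjusted p of 0.05, in order of log2 fold change, on linear axes that start at 0. Each point is 1 mouse (n = 6 per group), and the bars give the mean and SD; Ppp1r10 and Cyp2c37 are the genes whose groups overlap.

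In the reference annotation GENCODE M21 on GRCm38, the same assembly as mm10, the genes that rose lie as follows. Cyp2c40 (ENSMUSG00000025004) spans chromosome 19, 39767071 to 39812814, on the minus strand, Osgin1 (ENSMUSG00000074063) chromosome 8, 119434124 to 119446256, and Hes1 (ENSMUSG00000022528) chromosome 16, 30064384 to 30067796. Cbx2 (ENSMUSG00000025577) spans chromosome 11, 119022962 to 119031270, and Stard13 (ENSMUSG00000016128) chromosome 5, 151037510 to 151233836. Of the genes that fell, Serpina7 (ENSMUSG00000031271) spans chromosome X, 139079257 to 139085236. Ccrn4l (ENSMUSG00000023087) spans chromosome 3, 51224447 to 51251644, Slco1a4 (ENSMUSG00000030237) chromosome 6, 141805440 to 141856199, and Slc38a2 (ENSMUSG00000022462) chromosome 15, 96687392 to 96699730. Ppp1r10 (ENSMUSG00000039220) lies on chromosome 17, 35916434 to 35932283, Dnajb4 (ENSMUSG00000028035) on chromosome 3, 152178511 to 152210302, and Cyp2c37 (ENSMUSG00000042248) on chromosome 19, 39992424 to 40012243. All 12 are annotated as protein-coding, and the counts are over the exons of each gene.

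Genes known to be higher in male than in female mouse liver were mostly higher with ghrelin. Of the 29 measured members, 24 had a positive and 5 a negative log2 fold change, with a median of 0.45. The list rose against the other genes by camera with a preset correlation (adjusted p = 3.25e-13), and had an adjusted p = 0.206 with an estimated correlation. No member passed over all genes tested, and 16 higher and 1 lower passed when adjusted over the list alone. Gstp2, a glutathione transferase, had a log2 fold change of 0.92 (SE 0.18, 1.98 ± 0.361 against 3.75 ± 0.943 CPM), Serpina1e, a serine protease inhibitor, of 0.48 (SE 0.11), Gstp1 of 0.55 (SE 0.14) and C8b, a complement component, of 0.42 (SE 0.11). Gstp1 and Gstp2 are close paralogs and their split of reads is uncertain. Cyp4a12a, a fatty acid hydroxylase, had 0.45 (SE 0.14), Elovl3, a fatty acid elongase, 0.75 (SE 0.24) and Cyp7b1, an oxysterol hydroxylase, 0.80 (SE 0.29). Hsd3b5, a steroid dehydrogenase, had 0.13 (SE 0.27) and Slco1a1, an organic anion transporter, -0.07 (SE 0.07).

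The major urinary proteins, pheromone carriers made in larger amounts by male liver, were shifted the same way. Of 17 measured members 16 were positive, with a median log2 fold change of 0.73 (camera adjusted p = 1.52e-11, and adjusted p = 0.301 with an estimated correlation). None passed over all genes and 9 passed when adjusted over the list alone. The mean log2 CPM of the list was 4.58 to 4.92 in PBS 1 to PBS 4. It was 6.14 in PBS 5 and 6.43 in PBS 6, within the ghrelin range of 5.18 to 6.60. By this mean per animal the list did not pass (exact two-sided permutation p = 0.0325, adjusted 0.214 over the lists). Mup20 went from 2086 ± 566 to 3002 ± 514 CPM (log2 fold change 0.53, SE 0.16) and Mup7 from 481 ± 187 to 797 ± 150 CPM (0.73, SE 0.21). Mup1 had a log2 fold change of 0.91 (SE 0.23) and Mup21 of 0.40 (SE 0.13). Many genes of this family are near-identical copies and the treatment of shared reads is not known, so the value of a single member is uncertain.

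Genes known to be higher in female liver were mostly lower with ghrelin, with exceptions among the largest changes. Of 23 measured members 19 were negative and 4 positive, with a median log2 fold change of -0.48 (camera adjusted p = 6.93e-04, and adjusted p = 0.593 with an estimated correlation). Over all genes Slco1a4 fell and Cyp2c40 rose; adjusted over the list alone, 3 members were higher and 5 lower. The 3 higher members were Cyp2c40, Cyp2c69 and Dct. Cyp2c69, which is near-identical to Cyp2c40, had 2.55 ± 0.773 CPM in PBS and 12.1 ± 12.2 CPM in ghrelin (log2 fold change 2.28, SE 0.48, adjusted p = 0.0956), and the 2 genes cannot be separated with certainty in these counts. Without ghrelin 4, which had 36.1 CPM, its log2 fold change was 1.54 (adjusted p = 0.0422). Dct, a dopachrome tautomerase, had a log2 fold change of 0.93 (SE 0.23, adjusted p = 0.136). Cyp17a1, a steroid hydroxylase, had -0.41 (SE 0.29). The strongly female-biased genes Cyp2b9, Cyp3a41a and Cux2 stayed below the count filter in these males, with 83, 4 and 101 counts over all libraries.

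The sex index, the mean log2 CPM of the male-biased genes minus that of the female-biased genes in each animal, was 4.12 ± 0.790 (SD, n = 6) in PBS and 4.97 ± 0.486 (SD, n = 6) in ghrelin. The difference of 0.84 (SE 0.38) had an exact two-sided permutation p of 0.0584 and did not pass the threshold. Two-sided exact p-values were 0.026 without PBS 5, 0.0281 without PBS 6 and 0.0346 without ghrelin 4, so the call depended on single libraries. PBS 2, PBS 5 and PBS 6, with indices of 4.24, 5.13 and 5.00, lay within the range of the ghrelin animals, whose lowest index was the 4.14 of ghrelin 4. The main axis of a principal component analysis (20.8% of the variance) had Saa2, Saa1 and Mt2 at its positive end and Moxd1, Bcl6 and Mup17 at its negative end. It was not separate from the sex index, since male-biased genes of the list (Moxd1, Ugt2b38, Selenbp2) were among the genes at its negative end and female-biased ones (Cyp2b10, Slc16a5, Tox, Abcd2) at its positive end. PBS 4 (31.2), PBS 3 (23.1), PBS 2 (16.9) and ghrelin 4 (7.74) lay furthest on its positive side, and the groups differed by -17.9 on it (exact two-sided permutation p = 0.0584, adjusted 0.117 over 4 axes tested).

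**Figure D2:**
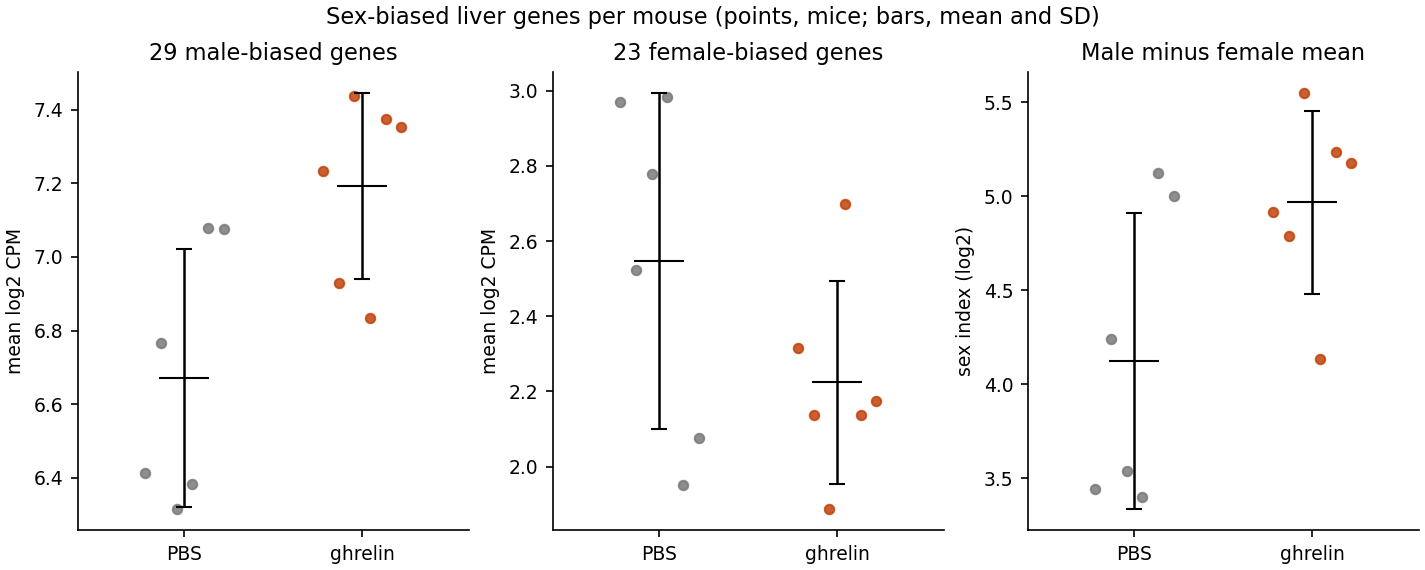
Mean log2 CPM of the 29 measured male-biased genes, of the 23 measured female-biased genes, and their difference, the sex index, for each mouse (points, n = 6 per group), with mean and SD as bars. The vertical axes do not start at 0; the index averages 4.12 in PBS and 4.97 in ghrelin, and 3 PBS mice lie within the range of the ghrelin mice.

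Genes of growth hormone and STAT5 signalling showed no common shift: 9 of 18 measured members were positive and 9 negative (camera adjusted p = 0.56), none passed over all genes, and 1 passed when adjusted over the list alone. That member was Stat5a, a transcription factor activated by growth hormone, at 7.48 ± 0.762 CPM in PBS and 11.2 ± 2.81 CPM in ghrelin (log2 fold change 0.58, SE 0.14, adjusted p = 0.14). Stat5b had a log2 fold change of 0.29 (SE 0.10), Igf1, the main growth factor released by the liver under growth hormone, of -0.18 (SE 0.07) and Igfals, its binding partner in plasma, of 0.21 (SE 0.10). Onecut1 had -0.84 (SE 0.38). Feedback targets of the pathway varied widely between animals: Cish had a log2 fold change of -0.83 (SE 0.66), Bcl6 of 0.48 (SE 0.64) and Socs2 of -0.22 (SE 0.43). The ghrelin receptor gene Ghsr and the acyltransferase gene Mboat4 had 0 counts in every library, and Ghrl, which encodes ghrelin, had 2 counts in all. Taken as 3 counts over all libraries, the limit that a count of 0 allows was 0.0127 CPM, which covers counting error only. Of the 5 measured members of the ghrelin axis, 2 were positive and 3 negative (camera adjusted p = 0.782), and Enho, which encodes adropin, passed when adjusted over the list alone (log2 fold change 0.52, SE 0.17). Bche, a butyrylcholinesterase that cleaves ghrelin, had -0.28 (SE 0.11).

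Genes of glucose metabolism fell as a list. Of 21 measured members 16 were negative, with a median log2 fold change of -0.20 (camera adjusted p = 6.52e-05, and adjusted p = 0.206 with an estimated correlation); none passed over all genes, and 7 lower and 1 higher passed when adjusted over the list alone. Ppargc1a, a coactivator induced in fasting, went from 27.3 ± 7.68 to 13.2 ± 3.56 CPM (log2 fold change -1.06, SE 0.20, adjusted p = 0.0564). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, had 8.28 ± 5.38 CPM in PBS and 1.96 ± 1.16 CPM in ghrelin (log2 fold change -2.11, SE 0.47), and the related subunit Ppp1r3b had -0.55 (SE 0.13). Foxo1, a transcription factor restrained by insulin, had -0.35 (SE 0.09). Pck1, which catalyses a committed step of gluconeogenesis, had -0.06 (SE 0.13). Amino acid and urea metabolism also fell as a list (16 of 21 measured members negative, median -0.09, camera adjusted p = 4.35e-04, and adjusted p = 0.457 with an estimated correlation). None passed over all genes and 7 lower passed when adjusted over the list alone. Tat, a tyrosine aminotransferase, went from 2601 ± 464 to 1677 ± 369 CPM (log2 fold change -0.63, SE 0.14). Got1, an aspartate aminotransferase, had -0.54 (SE 0.14), Tdo2, which starts tryptophan breakdown, -0.34 (SE 0.10), and Aass, of lysine breakdown, -0.32 (SE 0.08).

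Genes of lipid synthesis were mostly lower. Of 24 measured members of cholesterol synthesis and uptake, 22 were negative, with a median log2 fold change of -0.22 (camera adjusted p = 1.41e-05, and adjusted p = 0.647 with an estimated correlation); none passed over all genes and 1 passed when adjusted over the list alone. Idi1, an isomerase of the isoprenoid pathway, had a log2 fold change of -0.45 (SE 0.14) and Sqle, the squalene epoxidase, of -0.41 (SE 0.16). In fatty acid and triglyceride synthesis 17 of 22 members were negative (median -0.16, camera adjusted p = 0.0124, and adjusted p = 0.647 with an estimated correlation), with none past the threshold over all genes or when adjusted over the list alone; the adjusted p was 0.0754 without PBS 5. Lpin1, a phosphatidate phosphatase, had a log2 fold change of -0.78 (SE 0.24), Fasn, the fatty acid synthase, of -0.57 (SE 0.19), Pparg of -0.79 (SE 0.23) and Agpat2 of 0.27 (SE 0.09). By the mean log2 CPM of the list per animal neither synthesis list passed. The exact two-sided permutation p was 0.149 (adjusted 0.4675) for cholesterol synthesis and uptake. For fatty acid and triglyceride synthesis it was 0.0887 (adjusted 0.418). The cholesterol means of PBS 2 (6.58), PBS 3 (6.46) and PBS 4 (6.73) lay within the ghrelin range of 6.33 to 6.84. Fatty acid oxidation and PPARA targets did not pass (17 of 26 positive, camera adjusted p = 0.259). Among them Plin2, a lipid droplet coat protein, had 0.58 (SE 0.18), Ppara 0.34 (SE 0.13), Creb3l3 0.26 (SE 0.10), Vnn1 -0.83 (SE 0.27) and Cpt1a 0.05 (SE 0.12).

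Xenobiotic metabolism fell as a list, with 24 of 27 measured members negative and a median log2 fold change of -0.17 (camera adjusted p = 1.57e-06, and adjusted p = 0.206 with an estimated correlation). Cyp2c37 fell over all genes, and 5 lower passed when adjusted over the list alone. Cyp2c29 went from 1366 ± 204 to 883 ± 144 CPM (log2 fold change -0.63, SE 0.12, adjusted p = 0.055), Cyp2c54 had -0.42 (SE 0.12) and Cyp3a11, a target of the pregnane X receptor, -0.79 (SE 0.22). Bile acid synthesis and transport did not pass (8 of 17 positive, camera adjusted p = 0.524). Abcc3, an export pump of the basolateral membrane, had -0.47 (SE 0.14), Slc10a1, the bile acid uptake transporter, -0.20 (SE 0.08) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, -0.38 (SE 0.51).

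The circadian clock list did not pass (9 of 22 positive, camera adjusted p = 0.111). Its 1 member past the threshold over all genes was Ccrn4l, and adjusted over the list alone 2 lower and 1 higher passed. Per1, a repressor of the clock that also responds to acute signals, had a log2 fold change of -0.57 (SE 0.12, adjusted p = 0.0985) and Nr1d1, a nuclear receptor that represses Arntl, 0.36 (SE 0.10). Arntl had 0.19 (SE 0.29), Dbp 0.13 (SE 0.38) and Usp2 -1.21 (SE 0.52). Glucocorticoid targets fell as a list (14 of 15 negative, median -0.34, camera adjusted p = 4.70e-05, and adjusted p = 0.206 with an estimated correlation), with 5 lower when adjusted over the list alone, Per1, Tat, Lpin1 and Sgk1 (-0.34, SE 0.10) among them. None of its members passed over all genes. The mean log2 CPM of the list per animal differed by -0.343 between groups. Its exact two-sided permutation p was 0.208 (adjusted 0.524 over the lists), so it did not pass.

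Immediate early genes fell as a list (13 of 17 negative, median -0.23, camera adjusted p = 0.0265, and adjusted p = 0.74 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, had a log2 fold change of -1.01 (SE 0.28) and was the member that passed when adjusted over the list alone; Atf3 had -1.94 (SE 0.66), and -0.67 without PBS 5. The call of the list was lost without PBS 5 (adjusted p = 0.341), ghrelin 3 (0.0727), ghrelin 4 (0.051) or ghrelin 6 (0.144), and also with a filter of at least 1 CPM in 6 libraries (0.0559), with voom (0.0564) and with voom and quality weights (0.1005). The unfolded protein response rose as a list (14 of 18 positive, median 0.24, camera adjusted p = 0.0265, and adjusted p = 0.647 with an estimated correlation), yet its single member past the threshold adjusted over the list alone was lower: Atf4, a transcription factor of the stress response, with -0.30 (SE 0.08). Creld2, a chaperone of the endoplasmic reticulum, had 1.04 (SE 0.34). The call was lost without PBS 3 (adjusted p = 0.0904), PBS 6 (0.0591), ghrelin 1 (0.0758), ghrelin 3 (0.115), ghrelin 5 (0.0605) or ghrelin 6 (0.114), and also with 1 surrogate variable (0.187) and with the acute phase covariate (0.0766). No member of either list passed over all genes. By the mean log2 CPM of the list per animal neither list passed. The exact two-sided permutation p was 0.238 for immediate early genes and 0.141 for the unfolded protein response. Heat shock response (6 of 14 positive, camera adjusted p = 0.68), nuclear-encoded oxidative phosphorylation (18 of 25 positive, 0.136) and proliferation (6 of 14 positive, 0.464) did not pass.

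Of the marker lists for cells of the liver, the neutrophil list alone passed by camera with the preset correlation. All 4 measured neutrophil and myeloid progenitor markers were lower, with a median log2 fold change of -0.99 (camera adjusted p = 2.06e-04, and adjusted p = 0.206 with an estimated correlation); none passed over all genes and 2 passed when adjusted over the list alone. Of the 11 markers in this list the others lay below the count filter. The mean log2 CPM of the 4 was -0.95 in ghrelin 3 and -1.12 in ghrelin 6. It was 0.063 to 0.54 in the other ghrelin libraries and 0.53 to 1.49 in PBS. By this mean the list did not pass (exact two-sided permutation p = 0.00433, adjusted 0.0714 over the lists). S100a8, a calcium-binding protein of neutrophils, had 1.98 ± 0.825 CPM in PBS and 0.743 ± 0.416 CPM in ghrelin (log2 fold change -1.44, SE 0.36), and S100a9 had -0.99 (SE 0.37). The camera adjusted p was 0.736 for Kupffer cell and macrophage markers, 0.68 for endothelial, 0.56 for stellate cell and fibroblast, 0.414 for cholangiocyte, 0.611 for T and NK cell, 0.592 for B and plasma cell, 0.329 for erythroid, 0.736 for adipocyte and 0.56 for hepatocyte markers. None of their members passed over all genes; adjusted over the list alone, 1 adipocyte marker was higher and 1 hepatocyte marker, Tat, was lower, and 0 passed in the others. Cd163, a scavenger receptor of Kupffer cells, had -0.44 (SE 0.20), Dcn, a proteoglycan of fibroblasts, -0.21 (SE 0.08) and Lrat, of stellate cells, 0.69 (SE 0.27). Pericentral (7 of 14 positive, camera adjusted p = 0.829) and periportal hepatocyte genes (3 of 14 positive, 0.397) did not pass as lists. None of their members passed over all genes; adjusted over the list alone, 2 pericentral genes were higher and 4 lower, and 1 periportal gene was higher and 2 lower. Among them Cyp2f2 had 0.37 (SE 0.09), Slc1a2 -0.33 (SE 0.11), Arg1 -0.25 (SE 0.08) and Cps1 -0.19 (SE 0.06). The interferon response (16 of 24 positive, camera adjusted p = 0.18) and the acute phase response (4 of 23 positive, 0.16) did not pass, with 0 members past the threshold over all genes or adjusted over the list alone. The mean log2 CPM of the acute phase genes was 8.16 ± 0.731 in PBS and 8.01 ± 0.53 in ghrelin (SD, n = 6). Of the acute phase genes Crp had -0.18 (SE 0.07), and Lcn2 ranged so widely that its log2 fold change of -1.42 had an SE of 0.79; it was -0.71 without PBS 4 and 0.064 without PBS 3, PBS 4 and ghrelin 4.

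Across the 33 lists tested, 12 passed by camera with the preset correlation, 0 of these with the estimated correlation and 0 by fry for a shared direction. The mean log2 CPM of each list per animal was also compared by exact two-sided permutation. The lowest p was 0.00433 (adjusted 0.0714 over the lists), for glucose metabolism and for neutrophil markers, so no list passed this test. The mixed form of fry asks whether members differ in any direction, also without comparing them with other genes. Of the lists that did not pass by camera, pericentral (adjusted p = 9.91e-04), periportal (0.0073), hepatocyte (0.0090), bile acid (0.0137) and clock genes (0.0394) passed it. Growth hormone and STAT5 signalling (0.0907) and the others did not. The median and the mean of the members differed in sign for fatty acid oxidation, pericentral, endothelial and hepatocyte lists, and the camera direction of the adipocyte list was up with a negative median. Some measured properties of the genes went with the log2 fold change. Across 12154 protein-coding genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.345 with GC content and of -0.16 with transcript length. The Spearman correlation of each library's deviations with GC content was -0.119 ± 0.184 in PBS and 0.121 ± 0.2 in ghrelin (SD, n = 6, exact two-sided permutation p = 0.0606) and did not pass. Of 214 genes annotated as antisense, 164 had a positive log2 fold change, with a median of 0.22; since the strand setting of the counting is not known, reads of these genes and of the genes they overlap cannot be separated with certainty. The next axis of the principal component analysis held 12.8% of the variance, with a group difference of 16.5 (exact two-sided permutation p = 0.0216) that did not pass when adjusted over the 4 axes tested (0.0866).

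**Figure D3:**
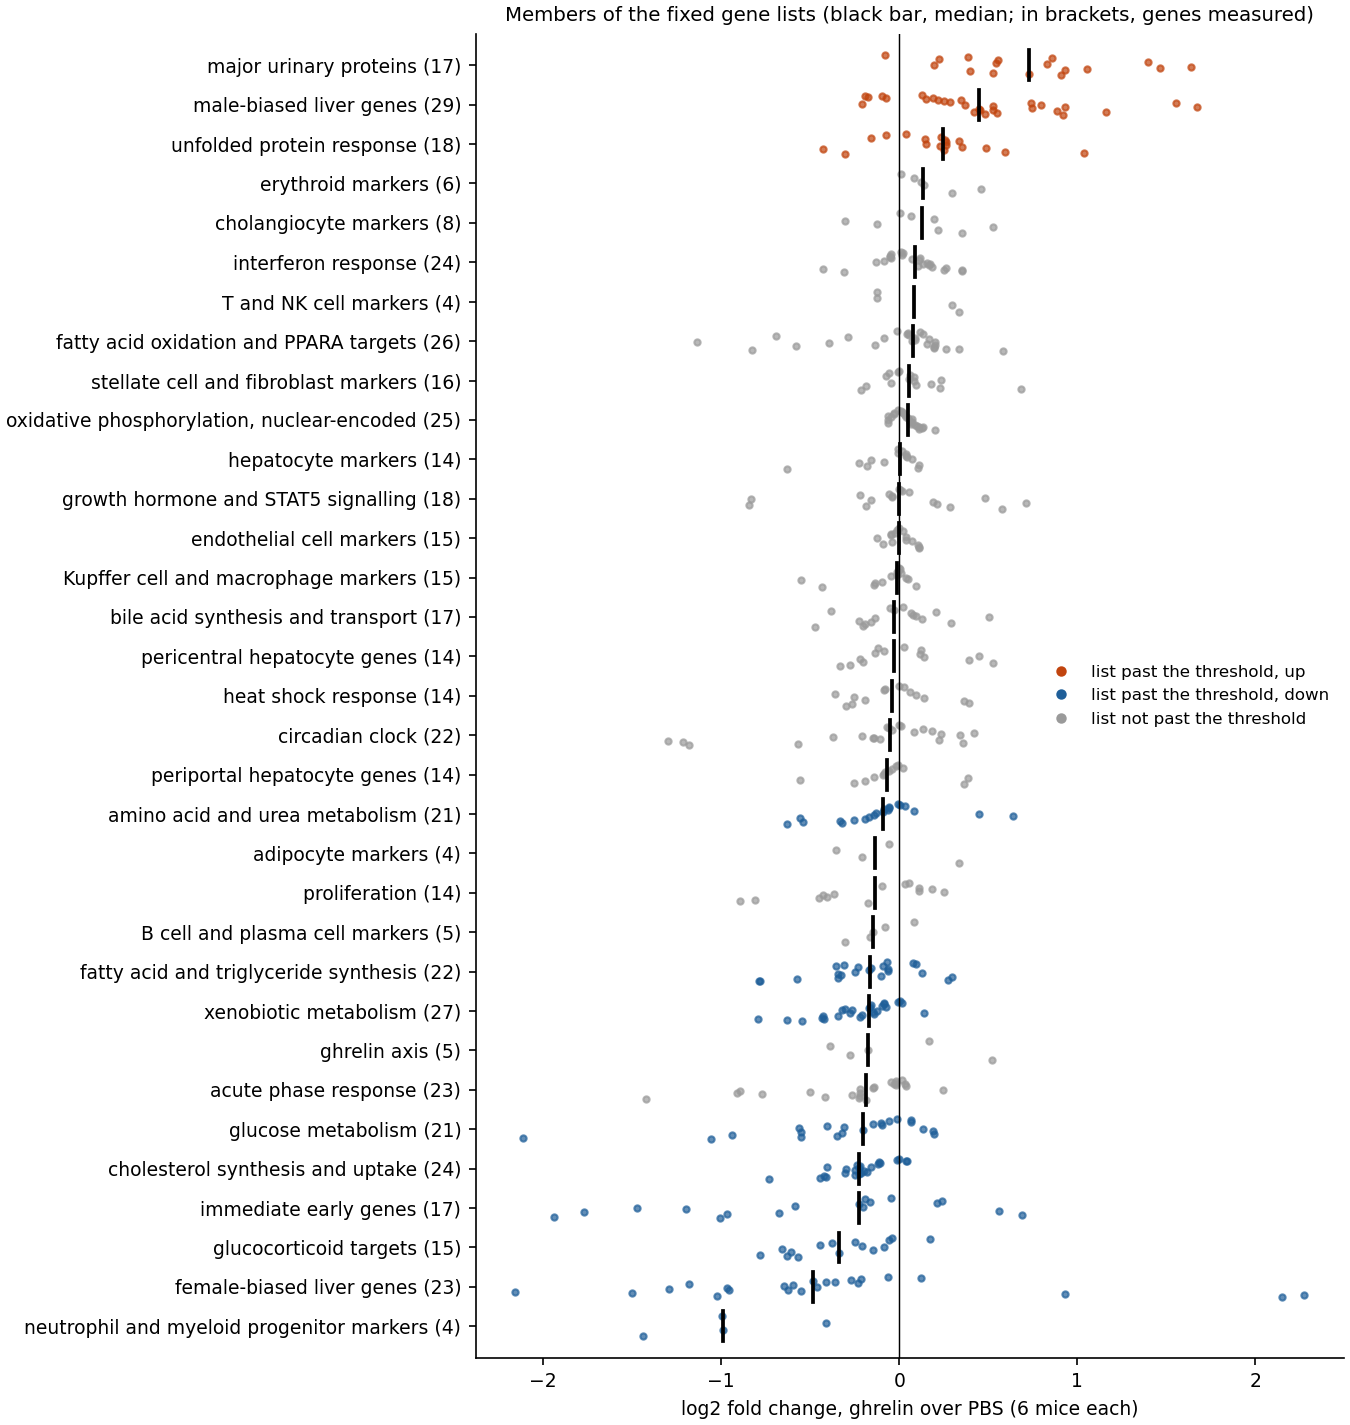
Log2 fold change (ghrelin over PBS, 6 mice each) of every measured member of the 33 gene lists fixed before the data were examined, with the median of each list as a black bar and the number measured in brackets. Orange marks lists that rose and blue lists that fell by camera with a preset correlation, and grey lists that did not pass; the medians run from -0.99 for neutrophil markers to 0.73 for major urinary proteins.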

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

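The tests of GC and length trends on the male-biased genes, of the acute phase, of library depth, of the Cyp2c reads and of the means of gene classes were chosen after the result was seen; the regrouping counts and the test of trends on antisense genes were set before. In 252 groups of 6 values, 12 held a library far from the others, where about 13 are expected by chance at 1 in 20. For ghrelin 4 these were fatty acid and triglyceride synthesis (mean log2 CPM 7.38, next 6.88), Fasn (496.7 CPM, next 333), Cyp2c37 (261 CPM, next 222) and Cyp2c69 (36.1 CPM, next 14.2). For ghrelin 2 they were the major urinary proteins (mean log2 CPM 5.18, next 6.17) and Vnn1 (9.23 CPM, next 5.82). For PBS 5 they were the unfolded protein response (mean log2 CPM 6.85, next 6.67), Atf3 (10.65 CPM, next 2.14) and S100a9 (5.48 CPM, next 3.15). The others were Plin2 in PBS 1 (345 CPM, next 258), the adipocyte markers in PBS 2 (mean log2 CPM 4.75, next 4.18) and Cyp7a1 in PBS 4 (95.2 CPM, next 34.4).

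The 15 called genes were set against other groupings of the same 12 libraries. Of 100 splits into 6 and 6, the real one included, 3 gave 15 or more calls, 91 of the other 99 gave 0, and the highest other split gave 135. The share of 3 in 100 is under the 0.05 level set beforehand to count against a chance split. It does not exclude one, since other splits gave 135 and 75 calls. Also, 0 genes were called without ghrelin 1 or without ghrelin 3. At an unadjusted p under 0.05, 2 of the 100 splits, the real one included, gave 1896 or more genes. The highest other split gave 1950. The split with 135 calls set PBS 1, PBS 5, PBS 6, ghrelin 1, ghrelin 3 and ghrelin 6 against the rest. This points to a structure of the samples other than treatment. The split followed the acute phase mean, which was 7.47 to 7.66 log2 CPM in the named libraries and 7.94 to 9.12 in the rest. Whether an acute phase response gave these calls was not tested.

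Male-biased liver genes had a mean log2 fold change of 0.483 with ghrelin. With GC and length trends removed from each library it was 0.496, a mean change per gene of 0.0132 (SE 0.00973), which argues against those trends as the whole cause. In 4 of 100 splits, the real one included, camera gave this list a p as small as the real 9.85e-15, the lowest other p being 7.44e-25. The camera p was under 0.05 in 64 of the 99 other splits, so with the preset correlation it overstates the evidence for this list. An acute phase response of some animals stays open: with the acute phase mean of each library as a covariate the ghrelin coefficient of the list mean was 0.477 (SE 0.151) against 0.521 (SE 0.176) without it, which is too wide to exclude a part of the difference, and an effect of ghrelin through growth hormone may add to it but was not tested.

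Antisense transcripts, a class singled out after its values were seen, were mostly positive: 76.6% of 214 antisense genes had a positive log2 fold change, against 48.5% of protein-coding genes. Other non-coding classes were also above that share, with 82.4% of 34 miscellaneous RNAs, 67.5% of 80 snRNAs, 67.1% of 255 snoRNAs and 56.1% of 123 lincRNAs, while processed pseudogenes had 46.9%. The antisense mean log2 CPM was 0.718 ± 0.109 in ghrelin and 0.483 ± 0.162 in PBS (SD, n = 6, exact permutation p = 0.0173), which did not pass when adjusted over the 7 gene classes (0.121). Trends with GC content and length as the cause are argued against for the antisense genes. Their median log2 fold change of 0.223 was 0.215 with both trends removed (SE of the change per gene 0.00369). This does not extend to snoRNAs, whose median of 0.0546 was 0.0118 with both trends removed. The median went from 0.169 to 0.142 for miscellaneous RNAs, from 0.0675 to 0.0515 for snRNAs and from 0.06 to 0.0739 for lincRNAs. The GC trend of the libraries did not pass between groups (exact permutation p = 0.0606), and a difference in library depth as its source cannot be told apart from the groups: the Spearman correlation of each library's deviations with GC content went with its total count at r = -0.571 (permutation p = 0.0542) and rho = -0.455 (permutation p = 0.141) over 12 libraries, at -0.371 within groups (permutation p = 0.265; 0.447 in PBS and -0.817 in ghrelin), and at r = -0.365 without ghrelin 2 and ghrelin 1. This was the sole relation of its family, so adjusted values are the same. Whether treatment or the counting of strands is involved was not tested.

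Of 13 measured Cyp2c genes 6 had a positive and 7 a negative log2 fold change, with the same signs under each of the other scalings. Cyp2c40 rose and Cyp2c37 fell over all genes. The other positive values were 2.28 (SE 0.48) for Cyp2c69, or 1.54 without ghrelin 4, 0.51 (SE 0.14) for Cyp2c70, and 0.04 to 0.08 for Cyp2c44, Cyp2c67 and Cyp2c68. Reads shared between Cyp2c40 and Cyp2c69 stay open, since the log2 ratio of their counts differed by -0.12 (SE 0.211) between groups, as it would if both counts may hold transcripts of a single gene. Reads of other Cyp2c genes and a response of the locus to ghrelin were not tested.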

How the results depend on the processing

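Removal of GC and length trends, the acute phase covariate and the fit without PBS 3, PBS 4 and ghrelin 4 were chosen after seeing the data, as was every alternative but the other list tests for the 10 lists past the threshold that are not the male- or female-biased list. The 15 called genes had the same sign in all alternatives, and the cause of the changes below was not tested. Genes called were 63 without a filter on low counts (28 higher, 35 lower, of 27410 genes tested), 9 with robust estimation (4 higher, 5 lower), 204 by DESeq2 (93 higher, 111 lower; 3024 adjusted p not given), 38 with 1 surrogate variable (17 higher, 21 lower) and 46 at an adjusted p under 0.1 (20 higher, 26 lower). They were 5 with GC and length trends removed (2 higher, 3 lower), 36 with the acute phase covariate (15 higher, 21 lower) and 20 without PBS 3, PBS 4 and ghrelin 4 (7 higher, 13 lower). The other scalings, the CPM filter, removal of the top 50 genes and voom gave 14 to 16. With trends removed the adjusted p of the 15 genes lay from 0.0453 to 0.0709. Leaving out 1 library gave 0 to 32 called genes, 0 to 16 higher and 0 to 16 lower.

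The male-biased list had an adjusted p of 0.206 with an estimated correlation and 0.101 by fry, the female-biased list 0.593 and 0.478. In the other alternatives both lists kept direction and side of the threshold, with adjusted p from 2.50e-22 to 1.06e-09 and from 4.71e-07 to 0.0146. These alternatives all used camera with the preset correlation of 0.01, so they cannot test that assumption. The sex index was 0.699 to 1.10 higher in ghrelin when 1 library was left out, with exact permutation p from 0.026 to 0.104. DESeq2, voom, robust estimation and the surrogate variable, fixed as alternatives for it, were not run on it, and removal of the Mup genes leaves no value for their list. Genes with few counts could not be tested at this depth: 7 of 11 neutrophil markers had 0 to 93 counts over all libraries, which low expression gives as well.

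With a replicate block 58 genes were called (22 higher, 36 lower), 13 of them among the 15, and the sex index difference of 0.843, positive in all 6 numbers, had an exact permutation p of 0.0312, the smallest that 6 pairs can give. With the replicate block and trends removed there were 25 calls (11 higher, 14 lower) and a sex index difference of 0.817 with the same p. Same-numbered libraries correlated at -0.081 to 0.27, with 3 of 6 pairs over 0.1, and 1 of 6 correlated best with its own number. No label states a pairing, and these values neither establish nor exclude one. Alone, the block ended none of the 12 list calls; with trends removed as well, the adjusted p of the unfolded protein response was 0.0594, against 0.0293 with trends removed and no block.

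Some genes that had not passed the threshold turned sign. With quality weights Socs2 had 0.012, Dbp -0.10 and Cpt1a -0.0059. With 1 surrogate variable Hsd3b5 had -0.084. With GC and length trends removed Slco1a1 had 0.030, and with the replicate block added Slco1a1 had 0.030 and Dbp -0.032. Without PBS 3, PBS 4 and ghrelin 4, Hsd3b5 had -0.049, Cyp7a1 0.093 (from -0.38) and Lcn2 0.064 (from -1.42). With 1 library left out, Pck1 ranged from -0.15 to 0.0017, Hsd3b5 from -0.0044 to 0.30 (also -0.00021), Socs2 from -0.51 to 0.049, Cyp7a1 from -0.85 to 0.060, Dbp from -0.086 to 0.32 (also -0.042 and -0.0052), Cpt1a from -0.013 to 0.11 (also -0.012) and Arntl from -0.087 to 0.37.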

Other observations

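The test on Cish and Bcl6 was chosen after its values were seen. Those on thyroid hormone and CREB targets were set after the main results but before the means of their lists were seen. They were not fully blind: Thrsp, Me1, Klf9, Irs2 and G6pc among their members also belong to the fixed lists, whose gene values came with the main results. Cish, a feedback inhibitor induced within minutes by growth hormone, and Bcl6, a repressor that growth hormone lowers in male liver, divided the animals across treatment. Cish was 13.1 to 27.1 CPM in 5 libraries (PBS 2, PBS 3, PBS 4, ghrelin 2 and ghrelin 4), where Bcl6 was 4.99 to 17.0 CPM, and 0.99 to 4.60 CPM in the other 7, where Bcl6 was 31.8 to 73.9 CPM. Socs2 overlapped between the sets, with 4.48 to 30.4 CPM in the 5 libraries of high Cish and 3.34 to 26.6 CPM in the other 7. The acute phase mean was 7.94 to 9.12 log2 CPM in the 5 and 7.47 to 8.59 in the 7, and its part in the division was not tested. A candidate explanation is the time since the last growth hormone pulse of each animal. Within the 7 libraries of low Cish, Cish and Bcl6 had r = -0.655 (exact permutation p = 0.107, adjusted 0.214) and rho = -0.786 (exact permutation p = 0.048, adjusted 0.096), and r = -0.454 without ghrelin 3 and PBS 5. Cish and Socs2, which the same pulse would raise together, had r = -0.0575 (exact permutation p = 0.899) and rho = 0.0714 (exact permutation p = 0.906), and r = 0.40 without the same libraries. The pulse explanation stays open, since both correlations rest on few libraries chosen for low Cish, and 5 are too few to test within the others. The overlap of Socs2 between the sets is not what a shared rise would give.

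Serpina7 fell with ghrelin, and Dio1, a deiodinase that thyroid hormone induces, had a log2 fold change of 0.94 (SE 0.21, adjusted p = 0.115). Higher thyroid hormone action in the liver may link them, and would raise other targets. The 6 measured genes of a list without those that led to the idea had a mean log2 CPM of 5.83 ± 0.325 in ghrelin and 5.95 ± 0.336 in PBS (SD, n = 6), with an exact permutation p of 0.537, and 2 of 6 were positive. The predicted rise was not seen; a difference within the spread of the animals does not exclude the idea, although a p of 0.05 or more had been set beforehand to count against it.

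Ppargc1a, Tat and Per1, which had lower values with ghrelin, are targets of CREB, the factor activated by glucagon, and lower CREB signalling in the liver is a further hypothesis. The 8 measured genes of a list of other CREB targets had a mean log2 CPM of 4.15 ± 0.150 in ghrelin and 4.24 ± 0.311 in PBS (SD, n = 6), with an exact permutation p of 0.565 (adjusted 0.565 over both lists), and 3 of 8 were positive. The predicted fall was within the spread between animals, so the test leaves the hypothesis open.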
